A study of Plutella xylostella with 12 samples.

How the data were processed

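The data are small RNA sequencing libraries from whole larvae, 3 for each of 4 groups defined in the labels by dose (0.01 or 0.1 ppm chlorantraniliprole) and time (6 or 24 h). Per the labels' protocols, total RNA was taken from surviving larvae, libraries were made with a TruSeq small RNA kit and sequenced on an Illumina HiSeq. The values are counts per miRNA as deposited, in 1 file per library with a name and a count column, per the file headers. The mapper, the miRNA reference and any filter are not given in the sources used here. No molecular identifiers are named in the labels, so reads are not independent molecules and precision from counts covers counting error only.

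Each miRNA name fills several rows of a file, and what sets the rows apart is not stated. Counts were summed over the rows of a name, and the highest single row was used as an alternative. The lowest row value was 5 in each file, and between 8.83% and 14.5% of the rows of a library stood at it, so a missing name is not a measured 0, and no upper limit was computed for it. Rows under 10 counts held 1.72% to 3.82% of the counts of a library. No row lacked a name. Of 105 names, 57 were listed in all 12 libraries and 7 in a single library. In 2 names the files join 2 miRNAs, which cannot be told apart. Members of a family that differ in few bases (such as pxy-mir-14a-3p and pxy-mir-14b-3p) may share reads in a way that the sources used here do not state, so their values are uncertain to that extent. Names are given as in the files. The reference table at hand holds no miRNA entries, so no genomic positions are given.

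Total counts per library ran from 10714 to 41214, a ratio of 3.85, with 19692 for the second shallowest. These are totals of the listed rows, not of the sequencing runs, whose depth is not given in the sources used here. Libraries of the same group were compared by chi-square over miRNAs: each of the 12 pairs differed beyond sampling noise (chi-square per degree of freedom 2.36 to 11.8), so no pair was merged as a repeat of 1 library. That does not show that libraries of a group are independent, for which the labels, naming them biological replicates, are the source, since preparations of 1 sample could differ as much. Measures per library were compared by exact permutation tests, two-sided and stratified where averaged over dose or time. With 3 against 3 libraries the smallest p that such a test allows is 0.1.

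Differential abundance was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group with a minimum count of 10, TMM factors, glmQLFit and glmQLFTest on all 12 libraries with a mean for each group (8 residual degrees of freedom). There were 7 comparisons: high against low dose averaged over times, at 6 h and at 24 h, 24 h against 6 h averaged over doses, at the low and at the high dose, and the difference of the dose effects between times. P-values were adjusted over the 73 tested miRNAs by Benjamini-Hochberg with a threshold of 0.05, and 32 names were not tested. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. Group levels are TMM-normalised CPM. Lists of miRNAs were tested with camera (limma 3.58.1) with an estimated correlation, adjusted over lists and comparisons, where they had at least 3 tested members.

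Before the data were examined, the tests, the alternatives, 18 lists and the rule for named miRNAs were fixed. For the averaged dose and time comparisons the rule named up to 10 higher and 10 lower miRNAs past the threshold by p, filled up to 5 in each direction with ones said not to pass. In the other comparisons it named up to 5 in each direction past the threshold, or the 2 with the smallest p where none passed. It added the 10 most abundant miRNAs and up to 4 members of the muscle, let-7 complex, hormone and growth, and insecticide lists, with values in the averaged comparisons. The other lists were metabolism, the clusters of miR-2 with miR-13 and miR-71, of miR-277 with miR-317 and miR-34, of miR-275 with miR-305 and of miR-12 with miR-283 and miR-304, the miR-9 and miR-279 families, the Hox loci, midgut and tubule, nervous tissue, ovary and embryo, Lepidoptera, *P. xylostella* and plant miRNAs. The *P. xylostella* list is a number range and says nothing of function.

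Alternatives were DESeq2 1.42.0, RLE factors, library totals, upper quartile factors, no filter, at least 10 counts in every library, only miRNAs listed in all libraries, the replicate number as a block, limma-voom with sample weights, the highest single row, only the libraries of a comparison, and each library left out in turn. For lists, camera with a preset correlation of 0.01, fry and the block were tried. After the data were seen, 4 were added: rows thinned at random to the depth of the shallowest library, or to that of the second shallowest with the shallowest, low-dose replicate 2 at 6 h, left out, in each case with rows under 5 counts dropped again (20 draws, medians), the omission of 2 libraries at 6 h, and arm ratios for only the precursors with both arms listed in all libraries. Ratios of the 2 arms of a precursor were tested with limma on log2 values with a pseudocount of 0.5. The axis of the 6 h libraries is the leading component of log2 CPM after subtraction of the group means, over miRNAs with a mean of at least 15 counts; on it the scores of each dose sum to 0 by construction, so it does not show which dose a library resembles. For that, distances between libraries were taken over the same miRNAs with no mean removed.

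The procedure was tested on data simulated from the 73 miRNAs with 10 changed in each of 20 simulations. For the dose difference at 24 h it recovered 40% of 1.5-fold and 73% of 2-fold changes, with 9.6% of calls false. For the averaged dose difference it recovered 61% and 87% with 8.07% false, and for the averaged time difference 60% and 81% with 1.4% false. With no change, and with the depths and the row minimum of the real libraries, no comparison gave more than 1 call in any of 20 simulations. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for reading, exact tests and plots.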

Results

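Small RNA was sequenced from whole 3rd instar larvae of the diamondback moth *Plutella xylostella*, a pest of brassica crops, that had survived exposure to chlorantraniliprole. This diamide insecticide acts on the ryanodine receptor, the calcium release channel of muscle. The larvae came from the Waite strain, which the labels describe as susceptible to insecticides. They were exposed to 0.01 ppm (low dose) or 0.1 ppm (high dose) and collected after 6 h or 24 h, with 3 biological replicates for each dose and time. This gave 12 libraries in 4 groups. The labels also mention unexposed control larvae, which were not analysed here, so each comparison below is between doses or between times and none is against unexposed larvae. The study asked how larval microRNAs (miRNAs) respond to this insecticide.

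Total miRNA counts per library ranged from 10714, in low-dose replicate 2 at 6 h, to 41214, in low-dose replicate 3 at 24 h. Mean totals were 20592 ± 9983 (SD, n = 3) at the low dose and 23707 ± 3479 at the high dose after 6 h, and 40038 ± 1990 and 34538 ± 5853 after 24 h. Averaged over doses, the 24 h libraries held 15139 more counts and listed 12 more miRNAs than the 6 h libraries. The exact stratified permutation p for the totals was 0.005, the smallest that the 400 regroupings can give, and 0.07 after Benjamini-Hochberg adjustment over 42 tests of library measures. Between doses the totals differed by -1192.5 counts on average (exact permutation p = 0.745). Each library listed 59 to 90 miRNA names out of 105 found in all, and no row with fewer than 5 counts was present, so a miRNA that a library does not list may have been present below that level.

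The same few miRNAs made up most of the counts in every library, the 10 most abundant of each library taking 74.8% to 78.8%. On average over the 12 libraries, pxy-miR-10-5p, encoded in the Hox complex of insects, took 17.7% ± 2.57 (SD, n = 12) of the counts. It was followed by pxy-miR-281-5p with 12.6% ± 1.64 and pxy-mir-31-5p with 12.4% ± 1.12. The other members of the 10 most abundant were pxy-mir-184-3p (8.15%), pxy-miR-263a-5p (7.05%), pxy-miR-274-5p (6.25%), pxy-miR-9b-5p (3.41%), pxy-mir-276-3p (3.19%), pxy-miR-279b-3p (3.18%) and pxy-miR-750-3p (2.40%). The muscle miRNA pxy-mir-1-3p stood far below these, at 1001 ± 508 (SD, n = 3) CPM (normalised counts scaled to a common library size) or less in each group. Of 105 names, 73 had enough counts to be tested, and these held at least 99.7% of the counts of each library. The biological coefficient of variation was 0.135.

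Averaged over both times, larvae given the high dose had more pxy-let-7-5p and pxy-miR-8496-3p and less pxy-mir-317-3p and pxy-mir-278-5p than larvae given the low dose. Some averages join unlike values at 6 h and 24 h: 0.435 and -1.414 for pxy-mir-278-5p, 0.159 and 1.564 for pxy-miR-8496-3p, and 0.036 and -0.614 for pxy-miR-281-5p. For these the dose effect differed between times, as given below. The group means of pxy-miR-750-3p at the low and high dose were 21000 and 20890 CPM at 6 h, and 33340 and 21790 CPM at 24 h. Those of pxy-mir-317-3p were 3040 and 2168 CPM at 6 h, and 6341 and 1542 CPM at 24 h. Neither passed between doses at 6 h, and neither passed for the difference of the dose effects. The ecdysone-responsive timing miRNA pxy-let-7-5p was 1.53-fold higher (log2 fold change 0.61 ± 0.14 SE, adjusted p = 0.00551, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 6 against 6 libraries). The levels of pxy-miR-8496-3p, whose number lies in the range described from this moth, were 1.82-fold higher (0.86 ± 0.19, adjusted p = 0.00551). Those of pxy-mir-317-3p were 2.55-fold lower (-1.35 ± 0.29, adjusted p = 0.00551). Levels of pxy-mir-278-5p were 1.40-fold lower (-0.49 ± 0.11, adjusted p = 0.00692). In *Drosophila* mir-278 acts on insulin responsiveness and energy balance, but that role was not tied here to the 5p arm. In all, 10 miRNAs passed an adjusted p of 0.05, 3 higher and 7 lower, and 19 had an unadjusted p under 0.05. Of the other 6, pxy-miR-274-5p rose by a log2 of 0.27, and pxy-mir-279d-3p, pxy-miR-2a-3p, pxy-miR-750-3p, pxy-miR-281-5p and pxy-miR-9b-5p fell by 0.51, 0.36, 0.32, 0.29 and 0.27. The next 2 higher miRNAs, pxy-miR-308-3p (0.48, adjusted p = 0.08) and pxy-mir-12-5p (0.31, adjusted p = 0.117), did not pass. Among the other abundant miRNAs, none passed: the log2 fold change was 0.19 for pxy-miR-10-5p, 0.07 for pxy-mir-184-3p, -0.02 for pxy-mir-31-5p, -0.08 for pxy-mir-276-3p, -0.23 for pxy-miR-279b-3p and -0.26 for pxy-miR-263a-5p. With 1 library left out, some of these newly passed: pxy-miR-10-5p without low-dose replicate 2 (0.38) or high-dose replicate 1 (0.27) at 6 h, pxy-miR-263a-5p without high-dose replicate 1 at 6 h or at 24 h (-0.30 each), pxy-miR-308-3p without low-dose replicate 2 (0.71) or high-dose replicate 1 (0.58) at 6 h, and pxy-mir-12-5p without high-dose replicate 1 at 6 h (0.43). Weaker values were -0.113 for pxy-miR-263a-5p without high-dose replicate 3 at 24 h and -0.11 for pxy-miR-279b-3p without low-dose replicate 2 at 6 h.

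The split of these dose calls depended on the scaling of the libraries. In place of 3 higher and 7 lower it was 10 higher and 1 lower with upper quartile factors, which shifted the median of all tested miRNAs from -0.04 to 0.23, and 3 higher and 4 lower with library totals, with relative log expression (RLE) factors or in DESeq2. With upper quartile factors pxy-mir-278-5p (-0.20), pxy-mir-279d-3p (-0.24), pxy-miR-2a-3p (-0.09), pxy-miR-281-5p (-0.02), pxy-miR-750-3p (-0.04) and pxy-miR-9b-5p (-0.003) kept their sign without passing. With only the most abundant row counted, pxy-mir-278-5p, pxy-miR-2a-3p, pxy-miR-750-3p and pxy-miR-9b-5p did not pass, whereas the other calls did. When each library was left out in turn, pxy-let-7-5p, pxy-miR-274-5p, pxy-miR-8496-3p and pxy-mir-317-3p passed in each of the 12 fits, whereas pxy-mir-278-5p passed in 10, pxy-miR-2a-3p in 6, pxy-mir-279d-3p and pxy-miR-281-5p in 5, pxy-miR-750-3p in 3 and pxy-miR-9b-5p in 2. The value of pxy-miR-750-3p was -0.146 without low-dose replicate 1 at 6 h, and that of pxy-miR-9b-5p -0.152 without high-dose replicate 3 at 24 h. The count was 4 without low-dose replicate 2 at 24 h, 5 without low-dose replicate 1 or 3 at 6 h, low-dose replicate 1 or 3 at 24 h or high-dose replicate 3 at 24 h, and 16 without high-dose replicate 1 at 6 h.

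By list, 2 of the 10 dose calls were in the hormone and growth list and 2 in the insecticide list, with pxy-mir-278-5p in both lists. Both arms of a family count as members. Of 9 tested miRNAs of families linked in insects to ecdysone, juvenile hormone or insulin signalling, 2 fell (pxy-mir-278-5p and pxy-miR-281-5p), none rose and 7 did not pass. Their median log2 fold change was -0.29, and 4 passed when adjusted over the list alone. Their values included -0.10 for pxy-mir-14a-3p and -0.14 for pxy-mir-14b-3p. Of 14 miRNAs of families tied to insecticide response in insects, 2 fell (pxy-miR-2a-3p and pxy-mir-278-5p) and 12 did not pass. The median was -0.29, and 5 passed adjusted over the list alone. Neither list passed as a set against the other miRNAs with camera and an estimated correlation (adjusted p = 0.436 for each, 70 tests). The fry test, which asks only whether the members of a list move on balance in 1 direction, gave adjusted p = 0.00108 and 0.0144. It was run with TMM factors alone. Upper quartile factors moved the median of all tested miRNAs from -0.04 to 0.23, so the fry values may depend on the scaling. Of the let-7 complex, which is induced by ecdysone in insects, pxy-let-7-5p rose while pxy-let-7-3p (-1.14 ± 0.72 SE) and pxy-mir-100-3p (0.09 ± 0.11) did not pass, and 1 of the 3 passed adjusted over the list alone. The -3.65 for pxy-let-7-3p without high-dose replicate 2 at 6 h is not a measured fold, as that group then lists no count of it. The muscle list had 1 tested member, pxy-mir-1-3p, at 0.39 ± 0.30, which did not pass. Its value was 0.19 without high-dose replicate 3 at 24 h and 0.67 without low-dose replicate 3 at 6 h.

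In the remaining lists the dose calls averaged over times were few, and none of the lists large enough to test passed camera with an estimated correlation. Of the miR-279 family, 1 of 4 fell and 3 passed adjusted over the list alone (fry adjusted p = 0.00567). Of the 8 metabolism miRNAs, pxy-mir-278-5p fell, with 3 adjusted over the list alone. The cluster of miR-2, miR-13 and miR-71 had 1 of 4 lower and 2 adjusted over the list alone, and the miR-9 family 1 of 4 lower and 1 adjusted over the list alone. The cluster of miR-277, miR-317 and miR-34 had 2 tested members, of which pxy-mir-317-3p fell, and the midgut and tubule list 2, of which pxy-miR-281-5p fell. The cluster of miR-12, miR-283 and miR-304 (2 tested), the miRNAs of the Hox loci (4) and those described in Lepidoptera (3) had no call for dose. Of 14 tested miRNAs in the number range described from *P. xylostella*, pxy-miR-8496-3p rose and 13 did not pass. The lists for nervous tissue, for the cluster of miR-275 and miR-305, for ovary and embryo and for plant miRNAs had no member among the 105 names.

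The dose difference was clearest after 24 h, where 12 miRNAs passed, 5 higher and 7 lower at the high dose, with 21 at an unadjusted p under 0.05. The lowest adjusted p belonged to pxy-mir-278-5p, which fell from 15980 ± 703 (SD, n = 3) to 6014 ± 952 CPM, 2.66-fold (log2 -1.41 ± 0.16 SE, adjusted p = 2.14e-06, edgeR). The other arm of the same precursor, pxy-mir-278-3p, named here after its values were seen, did not pass (-0.26 ± 0.14, adjusted p = 0.275). Levels of pxy-mir-317-3p fell 4.14-fold, from 6341 ± 875 to 1542 ± 744 CPM (-2.05 ± 0.39, adjusted p = 0.000822). Also lower were pxy-miR-279b-3p (-0.65, adjusted p = 0.000437), pxy-miR-281-5p (-0.61, adjusted p = 0.000822) and pxy-miR-750-3p (-0.61, adjusted p = 0.00159). Those that rose were pxy-miR-8496-3p, from 960 ± 184 to 2855 ± 183 CPM (1.56 ± 0.26, adjusted p = 0.000343), pxy-let-7-5p, from 2267 ± 548 to 4057 ± 267 CPM (0.84 ± 0.17, adjusted p = 0.00116), pxy-miR-277-3p, which in *Drosophila* acts on branched-chain amino acid breakdown (0.72, adjusted p = 0.0142), pxy-miR-308-3p (0.76, adjusted p = 0.0303) and pxy-mir-12-5p (0.54, adjusted p = 0.0392). The 3 low-dose and 3 high-dose libraries did not overlap for any of the 12, which the test selects for (among miRNAs not selected by a test, chance gives it for 10%). When each library was left out in turn, 7 of the 12 passed in each fit, pxy-miR-750-3p, pxy-miR-308-3p and pxy-mir-12-5p in 9 of the 12 fits, and the 2 lower miRNAs not named here in 4 and 5. At 24 h, pxy-miR-308-3p was lost without low-dose replicate 1 or 3 or high-dose replicate 3, pxy-mir-12-5p without low-dose replicate 1 or high-dose replicate 1 or 3, and pxy-miR-750-3p without low-dose replicate 1 or 2 or high-dose replicate 3.

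At 24 h the hormone and growth list had 2 lower and 7 not passing, with 2 adjusted over the list alone, the miR-279 family had 2 lower of 4, and camera with an estimated correlation passed neither (adjusted p = 0.436 for each). Of the 2 tested members of the cluster of miR-277, miR-317 and miR-34, pxy-miR-277-3p rose and pxy-mir-317-3p fell. The split of 5 higher and 7 lower became 13 higher and 2 lower with upper quartile factors, with which the median moved from -0.16 to 0.21, and 7 higher and 4 lower with library totals. With upper quartile factors pxy-miR-279b-3p (-0.27), pxy-miR-281-5p (-0.24) and pxy-miR-750-3p (-0.24) no longer passed, and the last did not pass with library totals either (-0.39), whereas pxy-mir-278-5p, pxy-mir-317-3p, pxy-let-7-5p, pxy-miR-8496-3p and pxy-miR-277-3p passed under each of the 4 other scalings. The value for pxy-miR-8496-3p was 0.84 when only its most abundant row was counted. Leaving out low-dose replicate 1 or high-dose replicate 3 at 24 h left 7 calls, and leaving out high-dose replicate 2 gave 19.

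**Figure D1:**
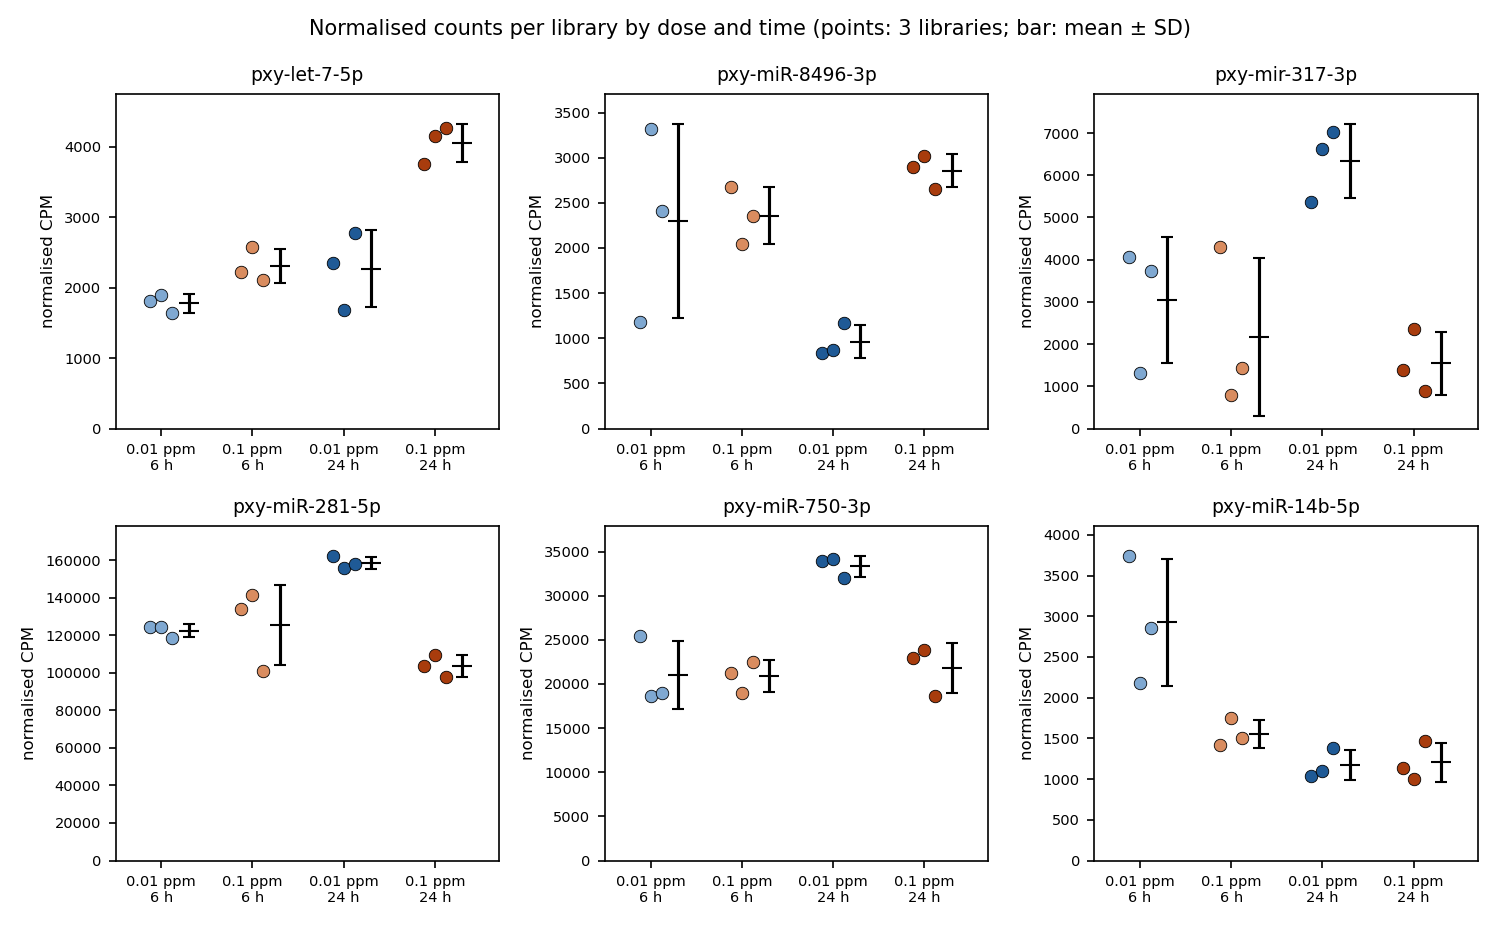
Normalised CPM of 6 miRNAs in each library (points) with the group mean and SD (bar, n = 3), by dose (0.01 or 0.1 ppm) and time (6 or 24 h). At 24 h the 2 doses do not overlap for pxy-let-7-5p, pxy-miR-8496-3p, pxy-mir-317-3p, pxy-miR-281-5p and pxy-miR-750-3p, and pxy-miR-14b-5p is highest in the low-dose 6 h group (2926 ± 783 CPM).

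**Figure D2:**
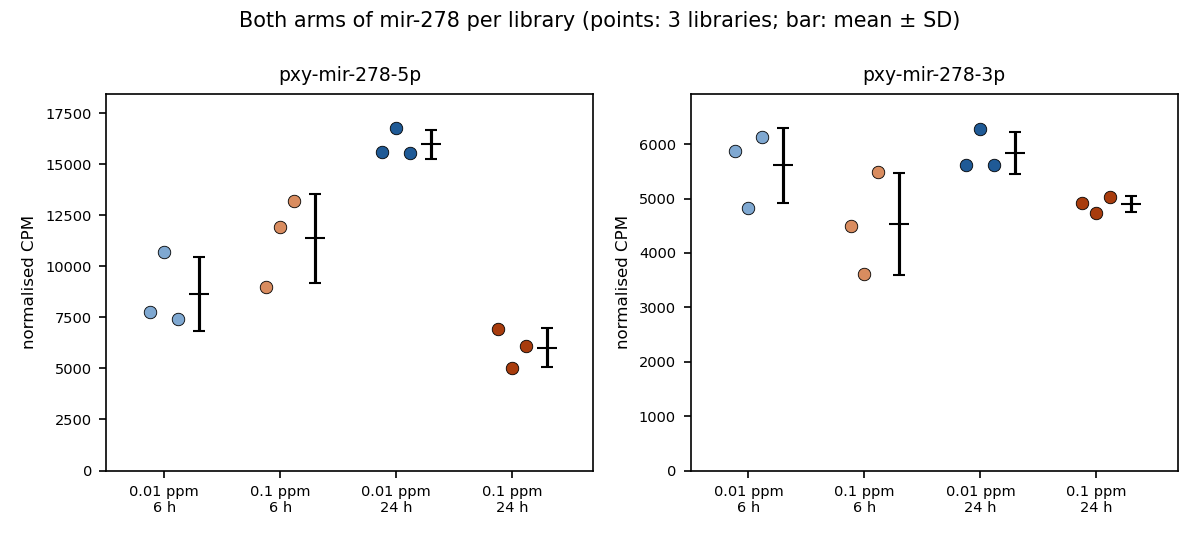
Normalised CPM of the 5p and 3p arms of mir-278 in each library (points) with the group mean and SD (bar, n = 3), by dose and time, with a separate scale for each arm. The 5p arm stands at 15980 ± 703 CPM in the low-dose and 6014 ± 952 CPM in the high-dose group at 24 h, and the 3p arm differs by a log2 of -0.26 that did not pass the test.

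After 6 h a single miRNA passed between doses. The level of pxy-miR-14b-5p fell from 2926 ± 783 (SD, n = 3) CPM at the low dose to 1555 ± 173 CPM at the high dose (log2 -0.96 ± 0.23 SE, adjusted p = 0.0437, edgeR). In *Drosophila* miR-14 acts on ecdysone signalling and fat metabolism, but that role was not tied here to the 5p arm. This arm took on average 0.17% of the counts, against 1.03% for pxy-mir-14b-3p. At 6 h, 13 miRNAs had an unadjusted p under 0.05, and DESeq2 called 0 with 12 at that level. The 2 higher miRNAs with the smallest p, pxy-miR-274-5p (0.35 ± 0.11) and pxy-miR-8521a-3p (0.61 ± 0.20), had adjusted p = 0.139 and did not pass. The first newly passed without high-dose replicate 1 at 6 h (0.42) and was 0.19 without high-dose replicate 3, and the second newly passed without low-dose replicate 1 (1.02). Counts of calls at 6 h followed the choice of libraries and scaling: 0 higher and 1 lower became 4 higher and 0 lower with upper quartile factors, 5 calls were made without low-dose replicate 2 and 7 without high-dose replicate 1. The call on pxy-miR-14b-5p was kept in 4 of the 12 fits that left out 1 library each. It was lost without low-dose replicate 1 or 3 or high-dose replicate 2 or 3 at 6 h, and also without any low-dose library or high-dose replicate 1 at 24 h, whose omission changed only the filter, the scaling and the shared spread.

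By their distance over 59 miRNAs (root mean square difference of log2 CPM, with no group mean removed), 2 of the 6 h libraries lay nearer to the other dose than to their own. Low-dose replicate 2 lay on average at 0.83 from the other low-dose and 0.719 from the high-dose libraries, and high-dose replicate 1 at 0.737 from the other high-dose and 0.707 from the low-dose libraries, whereas the other 4 lay nearer to their own dose. These distances were not tested, and the 2 libraries are the 2 shallowest of the 12, with 10714 and 19692 counts. Levels of pxy-mir-317-3p were higher in low-dose replicates 1 and 3 and high-dose replicate 1 than in the other 3. With low-dose replicate 2 and high-dose replicate 1 both left out, 8 miRNAs passed between doses at 6 h and 19 on average over both times, 9 of them among the 10 called with all libraries. That omission was chosen after the values were seen.

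For 6 miRNAs the dose difference itself differed between 6 h and 24 h. For pxy-mir-278-5p the log2 fold change was 0.43 ± 0.16 SE at 6 h and -1.41 ± 0.16 at 24 h, a difference of -1.85 ± 0.23 (adjusted p = 9.82e-06, edgeR interaction term). The difference was -0.84 for pxy-miR-279b-3p (adjusted p = 0.00206), -0.65 for pxy-miR-281-5p and -1.03 for pxy-miR-8521a-3p. It was 1.14 for pxy-miR-277-3p and 1.41 for pxy-miR-8496-3p. For the last of these it was 0.25 when only the most abundant row was counted, and did not pass. Across all 73 miRNAs the log2 fold changes for dose at 6 h and at 24 h had a Pearson r of 0.131 (permutation p = 0.253) and a Spearman rho of 0.185 (permutation p = 0.116), and miRNAs are not independent replicates. At 6 h pxy-mir-92b-5p was listed in no library and pxy-mir-iab-4-5p only in high-dose replicate 3, so their values there are not measured folds. The split of 2 higher and 4 lower became 4 higher and 2 lower with library totals and 2 higher and 1 lower with upper quartile factors. Without low-dose replicate 3 or high-dose replicate 3 at 6 h, 3 of these differences passed, and only those of pxy-mir-278-5p and pxy-miR-279b-3p passed in each of the 12 fits that left out 1 library, with 11 fits for pxy-miR-277-3p, 10 for pxy-miR-8496-3p and 6 each for pxy-miR-281-5p and pxy-miR-8521a-3p. With upper quartile factors the differences for pxy-miR-279b-3p, pxy-miR-281-5p and pxy-miR-8521a-3p did not pass. Those for pxy-miR-281-5p and pxy-miR-8521a-3p were also lost with library totals, and that for pxy-miR-8521a-3p in DESeq2.

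**Figure D3:**
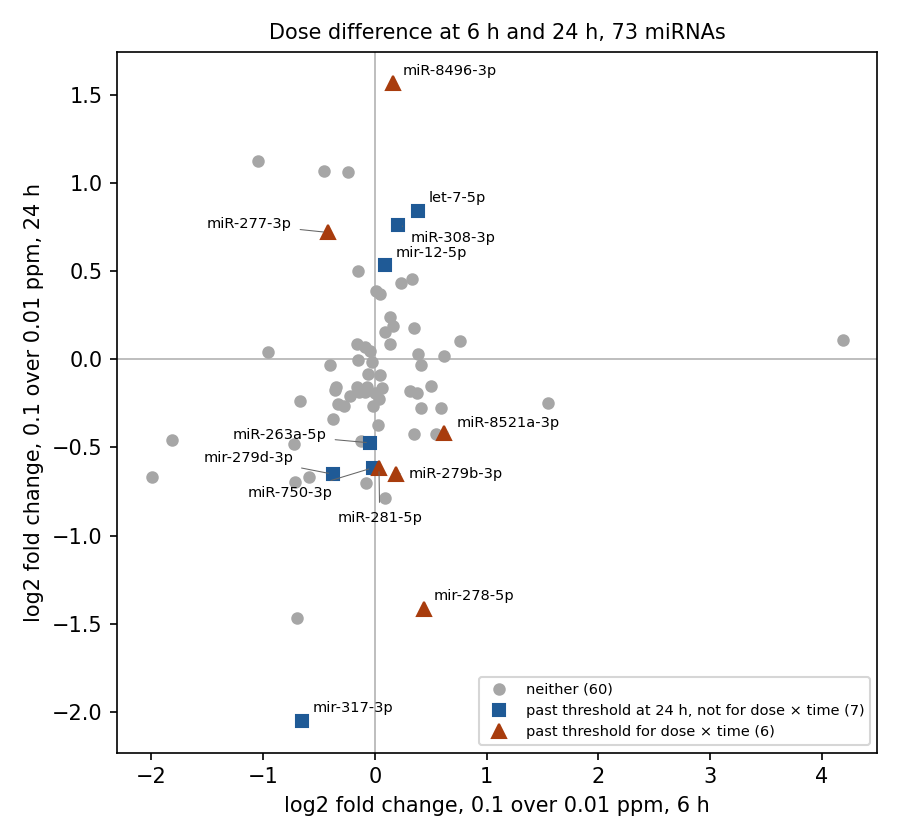
Log2 fold change of the high over the low dose at 6 h (horizontal axis) and at 24 h (vertical axis) for 73 miRNAs (points), with triangles for the 6 miRNAs whose dose difference differed between times and squares for the other miRNAs that passed at 24 h. The point for pxy-mir-278-5p lies at 0.43 and -1.41, and the Pearson r over all points is 0.131.

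Between times, averaged over doses, pxy-mir-316-5p, pxy-let-7-5p and pxy-miR-8521b-3p were higher after 24 h and pxy-miR-14b-5p and pxy-miR-9b-5p were lower. Levels of pxy-mir-316-5p rose 2.08-fold (log2 1.06 ± 0.24 SE, adjusted p = 0.00776, edgeR), those of pxy-let-7-5p 1.5-fold (0.59 ± 0.13, adjusted p = 0.00776) and those of pxy-miR-8521b-3p 2.25-fold (1.17 ± 0.28, adjusted p = 0.00776). Levels of pxy-miR-14b-5p fell 1.82-fold (-0.86 ± 0.17, adjusted p = 0.00399) and those of pxy-miR-9b-5p, of a family that acts in wing and sense organ development, 1.28-fold (-0.36 ± 0.09, adjusted p = 0.00776). Smaller rises were found for pxy-miR-750-3p (0.36, adjusted p = 0.0149) and pxy-miR-8521a-3p (0.45, adjusted p = 0.0326). These averages join unlike values. At the low dose the group means went from 21000 to 33340 CPM and from 2377 to 4930 CPM. At the high dose they went from 20890 to 21790 CPM and from 3857 to 3714 CPM. The interaction passed for pxy-miR-8521a-3p but not for pxy-miR-750-3p. The sixth call upward, pxy-mir-92b-5p (adjusted p = 0.0402), had 5 to 21 counts in each of the 6 libraries at 24 h and was listed in none of the 6 libraries at 6 h, so no fold is given. In all 8 miRNAs passed, 6 higher and 2 lower, and 19 had an unadjusted p under 0.05. The next lower miRNAs, pxy-miR-263a-5p (-0.28), pxy-miR-8496-3p (-0.42) and pxy-miR-2a-3p (-0.20), did not pass. The other abundant miRNAs lay between -0.16, for pxy-mir-31-5p, and 0.23, for pxy-miR-10-5p, and did not pass either. With 1 library left out, pxy-miR-263a-5p newly passed in 6 of the 12 fits (up to -0.40, without high-dose replicate 1 at 24 h), pxy-mir-31-5p without high-dose replicate 1 at 6 h or at 24 h (-0.27 and -0.26), and 3 others in 1 fit each: pxy-miR-8496-3p without low-dose replicate 1 at 6 h (-0.66), pxy-miR-2a-3p without high-dose replicate 3 at 6 h (-0.31) and pxy-miR-10-5p without low-dose replicate 2 at 6 h (0.30). The value of pxy-miR-10-5p was 0.10 without high-dose replicate 1 at 6 h.

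By list, the let-7 complex had 1 of 3 higher with time, pxy-let-7-5p, with 0.04 ± 0.66 SE for pxy-let-7-3p and 0.25 ± 0.11 for pxy-mir-100-3p (0.13 without low-dose replicate 3 at 24 h). The 2.50 for pxy-let-7-3p without high-dose replicate 2 at 6 h is not a measured fold, as that group then lists no count of it. Of 14 miRNAs in the range described from *P. xylostella*, 2 rose (pxy-miR-8521a-3p and pxy-miR-8521b-3p) and 12 did not pass. Of 9 hormone and growth miRNAs 1 fell, pxy-miR-14b-5p, with values of 0.27 for pxy-mir-14a-3p (0.30, and newly passing, without low-dose replicate 2 at 6 h), 0.05 for pxy-mir-14b-3p, 0.05 for pxy-miR-281-5p and -0.003 for pxy-mir-278-5p. The last joins 0.92 at the low dose and -0.93 at the high dose, which both passed. Group means of pxy-miR-281-5p went from 122300 to 158600 CPM at the low dose and from 125400 to 103600 CPM at the high dose. Of the 14 miRNAs of the insecticide list 1 fell, pxy-miR-14b-5p, and 1 passed upward, pxy-mir-92b-5p. The latter was listed in no library at 6 h, so depth and time cannot be told apart for it. Of the miR-9 family 1 of 4 fell, and the muscle miRNA pxy-mir-1-3p had 0.11 ± 0.30. Camera with an estimated correlation passed no list for any of the 7 comparisons (lowest adjusted p 0.436, 70 tests, and 0 also with a preset correlation), whereas fry passed 21 of the 70.

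At the low dose 14 miRNAs passed, 10 higher and 4 lower after 24 h, with 21 at an unadjusted p under 0.05. The higher ones were led by pxy-mir-278-5p (0.92 ± 0.16, adjusted p = 0.000582), pxy-miR-8521a-3p (0.97, adjusted p = 0.00175), pxy-miR-750-3p (0.65, adjusted p = 0.00175), pxy-miR-8521b-3p (1.501, adjusted p = 0.0209) and pxy-mir-100-3p (0.53, adjusted p = 0.035). The 4 lower ones were pxy-miR-14b-5p (-1.36 ± 0.23, adjusted p = 0.000582), pxy-miR-8496-3p (-1.13, adjusted p = 0.014), pxy-miR-277-3p (-0.68, adjusted p = 0.035) and pxy-miR-9b-5p (-0.36, adjusted p = 0.0444). At the high dose 5 passed: pxy-let-7-5p (0.82 ± 0.18, adjusted p = 0.00559) and pxy-mir-316-5p (1.15, adjusted p = 0.0445) rose, and pxy-mir-278-5p (-0.93 ± 0.16, adjusted p = 0.00112), pxy-miR-279b-3p (-0.55, adjusted p = 0.00476) and pxy-miR-263a-5p (-0.50, adjusted p = 0.0393) fell. Of these calls at single doses, pxy-mir-100-3p at the low dose was kept in 4 of 12 fits with a library left out (0.28 without low-dose replicate 3 at 24 h) and in 4 of 12 alternatives, and pxy-mir-316-5p at the high dose in 3 of 12 fits and 6 of 11 alternatives, being lost in DESeq2, without a filter and with limma-voom. At the low dose, pxy-miR-8521b-3p was kept in 8 of the 12 fits, pxy-miR-9b-5p in 9, pxy-miR-277-3p in 10 and pxy-miR-750-3p in 11, and each of the 5 further higher miRNAs in 0 to 3. With only the most abundant row, pxy-miR-8496-3p (-0.40) and pxy-miR-8521b-3p did not pass at the low dose, and neither pxy-miR-8496-3p nor pxy-miR-277-3p passed there with the libraries of the comparison alone. With upper quartile factors the low-dose calls on pxy-miR-277-3p and pxy-miR-9b-5p and the high-dose calls on pxy-miR-279b-3p and pxy-miR-263a-5p were lost, and the last was kept in 9 of 12 fits and 6 of 12 alternatives. For the 6 miRNAs with an interaction the change with time differed between doses by the same term, and for the other miRNAs called at 1 dose alone that difference did not pass.

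The splits for time also moved with scaling. Averaged over doses, 6 higher and 2 lower became 5 and 3 with library totals or RLE factors and 7 and 5 in DESeq2. At the low dose 10 and 4 became 4 and 6 with library totals, 4 and 4 with RLE factors and 7 and 4 in DESeq2, and at the high dose 2 and 3 became 5 and 2 with library totals and 2 and 1 with upper quartile factors. With only the most abundant row counted, pxy-miR-8521b-3p (0.49), pxy-miR-8521a-3p (0.31) and pxy-miR-750-3p (0.36) no longer passed on average, and pxy-miR-8521a-3p was also lost in DESeq2, with RLE factors and with library totals. The count averaged over doses was 5 without low-dose replicate 3 at 6 h or low-dose replicate 1 at 24 h and 4 without low-dose replicate 3 at 24 h, and pxy-mir-316-5p, pxy-miR-8521b-3p, pxy-miR-14b-5p and pxy-miR-9b-5p passed in each of the 12 fits. The averaged call on pxy-let-7-5p was kept in 11 of these fits, that on pxy-mir-92b-5p in 5, that on pxy-miR-750-3p in 4 and that on pxy-miR-8521a-3p in 2. At the low dose the count was 5 to 9 without any 1 of 9 libraries, the exceptions being low-dose replicate 2 and high-dose replicate 1 at 6 h and high-dose replicate 2 at 24 h, and at the high dose it was 3 without high-dose replicate 3 at 24 h. When all libraries were thinned to the depth of the shallowest, the median count averaged over doses was 1.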

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

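The tests of the arms, of depth, of the 6 h axis and of the exchange of 2 libraries below were chosen after values they bear on were seen, apart from the test of the highest single row, the scaling test for pxy-mir-317-3p and the count of other splits.

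For 6 miRNAs the effect of dose differed between 6 h and 24 h by the interaction term of the edgeR fit. The log2 difference, 24 h minus 6 h, was -1.848 for pxy-mir-278-5p, -0.841 for pxy-miR-279b-3p, -0.650 for pxy-miR-281-5p and -1.032 for pxy-miR-8521a-3p. It was 1.141 for pxy-miR-277-3p and 1.405 for pxy-miR-8496-3p. Among 100 splits of the libraries within each time, the real one and others drawn at random, 7 gave 6 or more such miRNAs, the real one included, and the highest other gave 11, a share that does not exclude chance for the count. Each of the 6 others kept the 24 h libraries of a dose together, 5 of them with the doses exchanged, so they carry the dose difference at 24 h. The 85 drawn splits that mixed the doses at 24 h gave 0, but mixing removes that difference. Neither kind of split is a clean measure of chance for this term, and this division was made after the counts were seen. Chance thus stays open for the count.

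The pattern with the lowest p was the fall of pxy-mir-278-5p with dose at 24 h while pxy-mir-278-3p did not pass. Library scaling cancels in the ratio of the arms, and the log2 ratio of 5p to 3p differed by -1.166 ± 0.308 SE, high minus low dose, which argues against scaling as the whole cause, though its adjusted p was 0.0679 over the 91 arm tests (0.0149 over the 42 tests of precursors with both arms listed in all libraries), and with the most abundant rows the difference was -0.864 ± 0.389 (adjusted p = 0.289). Depth and the row minimum are argued against by a log2 fold change of -1.43 after thinning to the shallowest library, and a change in minor rows as the whole cause of the 5p fall by -1.248 for its most abundant row alone. A change in the ratio of the 2 arms with dose, for which the interaction on the arm ratio was -1.885 ± 0.436 (adjusted p = 0.036, and 0.117 with the most abundant rows), stays open as a hypothesis found and tested on the same libraries, as do reads shared with a related sequence, which were not tested.

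At 6 h, low-dose replicate 2 (mean distance 0.83 to its own and 0.719 to the other dose) and high-dose replicate 1 (0.737 and 0.707) lay nearer to the libraries of the other dose, and pxy-mir-317-3p, 4.14-fold lower with dose at 24 h, had a loading of 0.305 on the main axis within the groups, the fourth by size. Exchanging the 2 libraries gave the lowest biological coefficient of variation of the 10 splits of the 6 h libraries (0.116, against 0.135 as stated). It gave 17 calls for the averaged dose difference. Both follow from picking libraries that lie nearer to the other dose. The exchange called more than the stated split in 20 of 20 draws at a common depth, which argues against unequal depth and the row minimum as the whole cause. However, the pair was picked on the same libraries, and they are the 2 shallowest of the 12 (10714 and 19692 counts). Thinning does not undo the counting noise they hold. Exchanged labels may account for where the 2 libraries lie. The dose effects at 6 h and 24 h then correlated across miRNAs with r = 0.248, the highest of the 10 splits (0.140 for the next). That was below the 0.5 set for that reading. Another state of the larvae that differs within groups would give the same, so these cannot be told apart. For pxy-mir-317-3p at 24 h, the other miRNAs' loadings on the axis correlated with their fall at r = 0.401, which leaves open that the same state contributes, while other scalings (weakest -1.697) and thinning (-1.966) argue against scaling and depth. The groups are kept as labelled in each comparison.

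The 24 h libraries were deeper than the 6 h libraries, so depth could produce calls between times. For the 7 miRNAs called between times and listed at both, the log2 fold change after thinning to the second shallowest library, with the shallowest left out, was in the median 0.843 of that with all libraries unthinned (lowest 0.773), and after thinning all libraries to the shallowest it was 0.884 to 1.164 of it in the draws in which the miRNA was tested (4 of 20 for pxy-miR-8521b-3p, 16 for pxy-mir-316-5p), which argues against depth as the whole cause. For pxy-mir-92b-5p, listed only at 24 h, depth and time cannot be told apart, because at the depth of the shallowest library it passed the expression filter in 0 of 20 draws. What remains, time since exposure, growth of the larvae or time of day, was not separated by this design.

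Other splits of the libraries were also counted for the remaining comparisons. For the averaged dose difference 2 of 100 splits, drawn at random apart from the real one, gave 10 or more miRNAs, the real one included. That share, under 0.05, argues against chance for the averaged count as a whole. It does not show a dose effect at 6 h. The count is carried by the 24 h libraries: with these as stated, 3 of the 10 splits at 6 h gave 10 or more (17, 11 and the real 10), and the 93 drawn splits that mixed the doses at 24 h gave at most 1. The highest other of those drawn, with 17, was the exchange of low-dose replicate 2 and high-dose replicate 1 at 6 h, which points to a structure of the 6 h libraries. For the averaged time difference the real split was the only 1 of 100, drawn likewise, with 8 (highest other 6, with times exchanged in all high-dose libraries). That share, also under 0.05, argues against chance for this count as a whole, but 100 splits cannot exclude it. The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05: at 6 h the dose split gave 1 and the highest other 6 (2 splits gave 1 or more), at 24 h 12 and 0, for time at the low dose 14 and 0, and at the high dose 5 and 2 (the real split being the 1 with as many in these).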

How the results depend on the processing

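Thinning and the joint omission of 2 libraries were chosen after the data were seen; the other settings were fixed beforehand. Over the alternatives other than left-out libraries, 863 of 1054 named values kept their direction and side of the threshold, 114 no longer passed, 36 newly passed and 41 changed sign. With libraries left out in turn, 754 of 960 did so, 129 no longer passed, 21 newly passed and 56 changed sign. Each change of sign was of a value that had not passed, most of them near 0, and where no reason is given below the cause was not tested. Each call kept its sign under each alternative in which its miRNA was fitted, with thinning not included in that count. Depth limits these data: at the depth of the shallowest library most counts of calls were lower. Fits without a library of a group also leave that group with 2 and test other miRNAs.

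Counts of calls outside 1.5 times the reported ones were these. Dose at 6 h (1) gave 0 in DESeq2, with RLE factors, with miRNAs listed in all libraries, with the libraries of the comparison alone and when thinned to the shallowest library, 2 with library totals, 2 with the highest single row, 3 without a filter, 4 with upper quartile factors and 4 when thinned to the second shallowest library, a setting that also leaves out low-dose replicate 2 at 6 h, the shallowest (5 without it and unthinned). Time at the low dose (14) gave 8 with RLE factors, 6 with upper quartile factors, 7 with at least 10 counts in every library, where fewer miRNAs are tested, 8 with the highest single row and 8 with the libraries of the comparison alone. Time at the high dose (5) and the interaction (6) each gave 3 with upper quartile factors. With limma-voom dose at 24 h (12) gave 22, averaged time (8) gave 15 and the interaction 10. Averaged time gave 5 with at least 10 counts in every library. Thinned to the shallowest library, with fewer counts, averaged dose gave 4.5, dose at 24 h 7, averaged time 1, time at the low dose 8, time at the high dose 3 and the interaction 3.5. With low-dose replicate 2 and high-dose replicate 1 at 6 h left out, averaged dose gave 19, dose at 6 h 8, averaged time 15 and the interaction 12, and since the pair was picked for standing apart, a smaller spread follows by construction. Among list tests (0 with camera) fry, which does not compare a list with other miRNAs, gave 21.

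With each library left out, averaged dose gave 4 to 16 calls, dose at 6 h 0 to 7, dose at 24 h 7 to 19, averaged time 4 to 12, time at the low dose 5 to 13, time at the high dose 3 to 7 and the interaction 3 to 9.

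Replicate numbers are shared by the groups. Over all 18 pairs of same-numbered libraries, deviations from the group means had r from -0.321 to 0.37 (median -0.075, 5 over 0.1). The numbers were therefore not taken to pair the libraries. Between doses at 24 h, though, r was 0.056, 0.324 and 0.35 in order of replicate number, and at 6 h it was 0.37, 0.136 and -0.194. A pairing within 24 h is thus not excluded, and the block fitted a single replicate effect over both times. With the replicate block, dose at 6 h gave 0 calls, averaged dose 10, dose at 24 h 11, averaged time 7, time at the low dose 15, time at the high dose 4, the interaction 7 and the list tests 0. Called without it and not with it were pxy-miR-14b-5p for dose at 6 h, pxy-mir-12-5p for dose at 24 h, pxy-mir-92b-5p for averaged time and pxy-mir-316-5p for time at either dose.

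These log2 fold changes changed sign. For averaged dose, pxy-mir-31-5p (-0.023) was 0.044 in DESeq2, 0.045 with RLE factors, 0.026 with totals, 0.263 with upper quartile factors, 0.046 with at least 10 counts, 0.012 when listed in all, 0.065 with the highest row, 0.084 without the pair of libraries and 0.056 and 0.034 when thinned. With upper quartile factors, which raised the median, pxy-miR-263a-5p was 0.015, pxy-mir-276-3p 0.206, pxy-miR-279b-3p 0.051, pxy-mir-14a-3p 0.183 and pxy-mir-14b-3p 0.132. Further, pxy-mir-276-3p was 0.004 with the highest row and 0.019 without the pair, and pxy-mir-14a-3p 0.017 when thinned to the second shallowest. For averaged time, pxy-miR-274-5p (-0.012) was 0.073 with upper quartile factors, 0.007 with at least 10 counts, 0.024 when listed in all, 0.013 with voom, 0.014 with the highest row and 0.020 when thinned. The value of pxy-mir-276-3p (0.002) was -0.047 in DESeq2, -0.045 with RLE factors, -0.019 with totals, -0.044 without a filter, -0.039 without the pair and -0.001 when thinned. That of pxy-let-7-3p (0.038), not listed in 3 libraries, was -0.122 in DESeq2, -0.003 with RLE factors and -0.087 without a filter. That of pxy-mir-278-5p (-0.003) was 0.085 with upper quartile factors, 0.021 with at least 10 counts, 0.036 when listed in all, 0.075 with voom and 0.055 when thinned. Without the pair, pxy-mir-1-3p was -0.019 and pxy-mir-14b-3p -0.033. The difference in miRNAs listed between doses at 6 h (1) was -1 when only those with at least 10 counts were taken.

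With each library left out, the averaged time values ranged from -0.323 to 2.500 for pxy-let-7-3p, -0.115 to 0.006 for pxy-miR-274-5p, -0.067 to 0.033 for pxy-miR-281-5p, -0.211 to 0.269 for pxy-mir-1-3p, -0.048 to 0.053 for pxy-mir-14b-3p, -0.029 to 0.183 for pxy-mir-184-3p, -0.094 to -0.013 for pxy-mir-276-3p and -0.145 to 0.055 for pxy-mir-278-5p. The 2.500 is without high-dose replicate 2 at 6 h and not a measured fold, as that group then lists no count of pxy-let-7-3p. The averaged dose values ranged from -0.123 to 0.060 for pxy-mir-14a-3p, -0.093 to 0.022 for pxy-mir-276-3p and -0.053 to 0.076 for pxy-mir-31-5p. Not applicable were a pseudocount and a filter on normalised values, as the values are counts, and the libraries of the comparison alone for the averaged comparisons and the interaction.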

Other observations

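The ratio of the arms of a precursor was compared for the 13 precursors with both arms tested, in 91 tests, on the hypothesis that arms change apart with dose or time, which was chosen after the counts of both arms had been seen. The adjusted threshold was passed for 2 precursors, mir-278 and mir-92b, but the 5p arm of mir-92b was not listed at 6 h, so its ratio there is set by the pseudocount and is not a measured change. Among the 6 precursors with both arms listed in all libraries, mir-278 passed for the interaction (adjusted p = 0.00805 over 42 limma tests), for dose at 24 h (0.0149) and for time at the high dose (0.0269), and no other precursor passed. With only the most abundant row of each arm, none of these passed for mir-278 over the 91 tests: the log2 ratio changed by -1.867 ± 0.55 SE for the interaction (adjusted p = 0.117), -0.864 ± 0.389 for dose at 24 h and -0.958 ± 0.389 for time at the high dose (adjusted p = 0.289 for both). The 5p arm of mir-278 exceeded the 3p arm by a log2 of 1.45 ± 0.03 (SD, n = 3) in the low-dose and 0.29 ± 0.20 in the high-dose group at 24 h, and by 0.61 ± 0.47 and 1.32 ± 0.36 at 6 h. For most precursors 1 arm was far more abundant: the 5p arm of miR-281 exceeded the 3p arm by a log2 of 4.87 ± 0.03 to 5.56 ± 0.07, and the 5p arm of miR-10 by 5.77 ± 0.02 to 5.92 ± 0.39, over the 4 groups.

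Whether dose acts in the same direction at both times was tested, after the effects had been seen, by the correlation of the 2 sets of log2 fold changes, which come from different libraries. The Pearson r of 0.131 has a 95% interval across miRNAs of -0.10 to 0.35, and 45 of 73 miRNAs had the same sign, so a shared direction across miRNAs could be neither shown nor excluded, while for 6 miRNAs the effect of dose differed between times by the interaction term. The interval treats miRNAs as independent. The 73 include pxy-mir-92b-5p and pxy-mir-iab-4-5p, whose values at 6 h are not measured folds.

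At 24 h, 2 members of the list for the cluster of miR-277, miR-317 and miR-34 moved in opposite directions with dose, pxy-miR-277-3p (0.72) and pxy-mir-317-3p (-2.05). Whether their precursors lie together in this moth was not examined, as no positions were at hand. No explanation was tested.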
